A study of Mus musculus with 12 samples.

How the data were processed

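Gene expression was measured on 12 Illumina mouse bead arrays, 1 per sample, from total RNA of dendritic cells grown from bone marrow. Cells were wild type (WT) or lacked NFAT1 (knockout, KO), and were left unstimulated or stimulated with Pam3CSK4 for 2 h or 12 h. Each of the 6 groups had 2 arrays, and the group and replicate number of every array came from its label. The labels do not say whether the 2 samples of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. The strain of the mice and how the knockout was made are not given in the sources used here.

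The authors deposited, for each array, the linear signal intensity of 25697 probes without normalization, with a detection p-value for each probe. Biotin-labelled cRNA was made from the RNA, and GenomeStudio 2011.1 and R 2.15.1 were used, with their roles not given, per the labels' protocols. A background correction by the authors is not stated. The detection p-values in the deposited table moved in steps of 0.00125. A second deposited table, of values by probe, was not used in any comparison. Its values were between 3.87% and 4.98% of the same probe's signal at the median of each column, and smaller in proportion for bright probes, which is the pattern of an error over beads rather than of an expression level. Its column medians were 5.63 and 6.09 for unstimulated WT, 7.10 and 7.22 for WT at 2 h, 7.18 and 7.57 for WT at 12 h, 5.55 and 5.65 for unstimulated KO, 7.33 and 7.00 for KO at 2 h, and 7.57 and 7.34 for KO at 12 h. Its scale, centring and direction stay unknown. In that table the columns of the second WT array and the first KO array at 12 h were identical, and the column of the second KO array at 12 h followed the signal of the first (r = 0.983 across probes, against 0.977 with its own signal). In the signal table no arrays were identical.

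Signals were corrected for background by normexp with negative-control values inferred from the detection p-values, offset by 16, quantile normalized and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). A probe was kept where its detection p was under 0.05 on both arrays of at least 1 group. Of the 25697 probes, 23978 had 1 gene, 0 had several and 1719 were unnamed here. Entrez identifiers placed 23962 of the named probes in the RefSeq gene table of assembly GRCm38.p6, used only for current symbols and gene order, and 16 kept the array's symbol. Among 12341 kept probes the one with the highest mean over all arrays stood for each gene, which left 8967 genes to test of 16593 on the array. Values in the text are differences of mean log2 values with the standard error of the fit, and n = 2 arrays per group throughout. The small number of arrays limits the precision.

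limma was fitted with one mean per group over all 12 arrays, so that the groups shared one estimate of the spread (6 residual and 3.37 prior degrees of freedom). Tests were two-sided with Benjamini-Hochberg adjustment over the 8967 genes, and a gene was called where its adjusted p was under 0.05. The 11 contrasts were KO against WT in each condition and averaged over the 3 conditions, Pam3CSK4 against no stimulation in each genotype at each time, 12 h against 2 h in WT cells, and the difference between the genotypes' responses at 2 h and at 12 h. A probe not detected on either array of a group has only a bound there. Such a gene is given as at least N-fold, from the mean of the bright group against the mean of, per array, the higher of the lowest detected signal and the probe's own, all after normalization.

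The 30 gene lists (responses, pathways, cell type markers and genes next to Nfatc2) were written before the data were examined, as were the contrasts and their tests, most alternatives and the rule for which genes are named. Most tests of technical explanations were written after the result each concerns had been seen. Each list was tested with camera in limma with a preset correlation of 0.01 between genes, and again with the correlation estimated from the data, with adjustment over the 30 lists. Besides adjustment over all genes, members were counted with p adjusted over the list alone. By the rule, each contrast names up to 8 called genes with the highest and 8 with the lowest change among genes detected on all arrays concerned, up to 3 in each direction not detected in one group, and up to 4 called members of each list with the smallest adjusted p, or up to 2 members as values where none was called. Gene models without a proper symbol may be left out, and Nfatc2 is given by every probe. A gene named in a genotype or stimulation contrast without a remark kept its call when any 1 array was left out. Other probes of a gene were compared, and disagreements are stated.

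The fit and the list test were tried on simulated normalized log2 values with 200 of 8967 genes changed. Noise was drawn independently for each gene. Normalization, the probe filter and the choice of probe were not covered. For KO against WT in unstimulated cells 11.5%, 91.0% and 99.5% of changes of 0.5, 1 and 2 on the log2 scale were called, for the mean over conditions 87.0%, 99.5% and 100%, and for the difference between responses at 2 h 0%, 68.0% and 98.0%. A planted list of 20 genes shifted by 0.5 was called in each of these 3 comparisons. Its genes varied independently, so the call says nothing of lists whose genes vary together. Alternatives were no background correction, median scaling, a detection p under 0.01, no filter, all kept probes, a variance trend with robust fitting, only the arrays of the contrast, the replicate number as a block, a 2-fold minimum, and each array left out in turn. Chosen after seeing the data were leaving out both 12 h arrays with identical columns and leaving out the 100 tested genes nearest Nfatc2. Figures were drawn with matplotlib 3.10.9.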

Results

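Gene expression was measured in dendritic cells grown from mouse bone marrow. The cells were wild type (WT) or lacked NFAT1 (KO), a calcium-regulated transcription factor encoded by Nfatc2. They were unstimulated or had been given Pam3CSK4, a synthetic lipopeptide that activates Toll-like receptor (TLR) 2 together with TLR1, for 2 h or 12 h. Each of the 6 groups had 2 arrays. Between 43.9% and 49.3% of the 25697 probes were detected per array, and the median signal was between 123 and 141. The 2 arrays of a group correlated at 0.994 to 0.996 across the 8967 genes tested, after normalization. Values below are log2 differences ± the standard error of the fit with n = 2 arrays per group, and of the 8967 genes tested those with an adjusted p under 0.05 were called.

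Nfatc2 itself was not detected. Its 5 probes gave 60 values, of which 0 were detected, with a smallest detection p of 0.120 and signals from 93.3 to 133. This held in WT cells as in KO cells, so the transcript could not be used to check the genotype labels. Across all genes the first principal component, with 57.1% of the variance, parted unstimulated from stimulated cells, and the second, with 30.2%, parted 2 h from 12 h. The third, with 5.1%, parted the genotypes, with scores from 5.25 to 19.1 for the 6 WT arrays and from -14.6 to -4.45 for the 6 KO arrays. At 12 h the KO arrays lay at 26.6 and 28.8 on the second component, against 37.8 and 39.0 for WT.

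**Figure D1:**
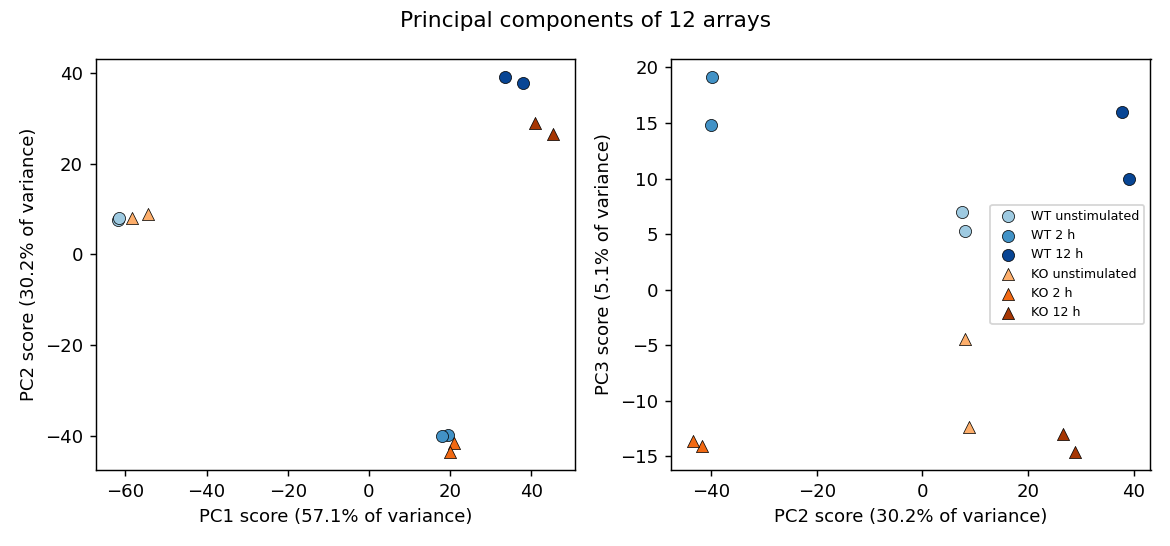
Principal component scores of the 12 arrays (circles WT, triangles KO, darker shades for later times), with the second component against the first and the third against the second. The 6 WT arrays have scores of 5.25 or more on the third component and the 6 KO arrays scores of -4.45 or less.

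The first question was how WT cells given Pam3CSK4 differed from unstimulated WT cells. The labels give no time for unstimulated cells, and the same unstimulated group of each genotype was the reference at 2 h and 12 h. Changes with time in culture could thus not be told apart from effects of Pam3CSK4. At 2 h the largest rises among genes detected throughout were in interferon-induced antiviral genes, Ifit2 by 7.77 ± 0.24, Rsad2 by 7.36 ± 0.17, Cmpk2 by 7.26 ± 0.19 and Ifit3 by 7.11 ± 0.16. Cd40, a costimulatory receptor, rose by 6.77 ± 0.10, and Il6, an inflammatory cytokine, by 6.39 ± 0.20. The chemokine gene Cxcl9 was at least 94.6-fold higher than in unstimulated cells, where it was not above background. Per1 and Per2, clock genes, fell by 4.27 ± 0.14 and 3.65 ± 0.22, with 1 of 2 other Per2 probes moving the same way past the threshold, and Dusp6, a phosphatase that acts on ERK, fell by 4.19 ± 0.23. The cannabinoid receptor gene Cnr2 was at least 14.8-fold lower. In all, 5726 genes were called, 2371 higher and 3355 lower. Median scaling in place of quantile normalization gave 1790 higher and 3902 lower, and moved the median over all genes from -0.12 to -0.27, so the changes are relative to the scaling.

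All 29 interferon-stimulated genes measured rose at 2 h in WT cells (median 4.42, or 4.29 with undetected members at their bound, adjusted p = 1.50e-22), 29 also when adjusted over the list alone. Of the 27 TLR primary response genes 26 rose and 1 did not pass, with a median of 2.41 (adjusted p = 8.88e-15), among them Bcl3 and Nfkb2, members of the NF-kB system, by 2.65 ± 0.09 and 2.67 ± 0.12. Of 23 cytokine genes 19 rose and 1 fell (median 2.53, adjusted p = 2.95e-09), with Il10 higher by 3.24 ± 0.12 and Il12a at least 29.0-fold. Chemokines (16 higher, 1 lower, 2 not passing, adjusted p = 2.77e-07), maturation genes (18, 2 and 2, adjusted p = 3.10e-08), inflammatory effectors (17, 1 and 5, adjusted p = 9.23e-07) and the oxidative stress response (11, 0 and 1, adjusted p = 2.40e-06) also rose as groups. For these 7 lists the adjusted p with an estimated correlation lay between 0.0552 and 0.072. Glycolysis genes fell, 14 of 18 (median -1.05, adjusted p = 8.52e-04, and adjusted p = 0.258 with an estimated correlation), with Pfkl lower by 1.82 and Egln3, an oxygen sensor, by 3.37.

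At 12 h in WT cells the interferon-stimulated genes were still the group with the smallest adjusted p, all 29 higher (median 3.44, adjusted p = 8.22e-18, and adjusted p = 0.113 with an estimated correlation). Irf7, a master regulator of type I interferon, rose by 6.61 ± 0.11. Ptges, which makes prostaglandin E2, rose by 6.22 ± 0.12 and Lcn2, an iron-binding antimicrobial protein, by 6.29 ± 0.38. Slc1a2, a glutamate transporter gene, was at least 116-fold higher than in unstimulated cells. Klf4, a macrophage-associated transcription factor, fell by 4.46 ± 0.26 and Mrc1, the mannose receptor, fell by 4.38 ± 0.19. Of the 12 oxidative stress genes 12 rose, including Nqo1 by 4.14 ± 0.14 (list median 2.78, adjusted p = 1.55e-07, and adjusted p = 0.113 with an estimated correlation). Among cell cycle genes 20 of 22 fell, including Aurka by 3.03 ± 0.13 and Plk1 by 2.66 ± 0.17 (median -1.71, or -1.5 with undetected members at their bound, adjusted p = 3.53e-06, and adjusted p = 0.268 with an estimated correlation). MHC class II genes were lower, 11 of 17 against 1 higher (median -0.62, adjusted p = 0.00966, and adjusted p = 0.113 with an estimated correlation), with H2-DMa lower by 2.33. That call ended with median scaling (adjusted p = 0.0565). The count was 5664 genes, 2691 higher and 2973 lower.

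From 2 h to 12 h in WT cells Cxcl5, a neutrophil attractant, rose by 4.85 ± 0.25 while Cxcl10, a T cell attractant, fell by 4.77 ± 0.46. Il23a fell by 4.10 ± 0.22 and Edn1, endothelin 1, by 4.69 ± 0.29, and Ptges rose further by 4.21 ± 0.12. Of the chemokine genes 11 fell and 6 rose (median -1.09, adjusted p = 0.0260, and adjusted p = 0.255 with an estimated correlation). Of the TLR primary response genes 15 fell and 3 rose (median -0.75, adjusted p = 5.10e-04, and adjusted p = 0.261 with an estimated correlation), and of the interferon-stimulated genes 19 fell and 1 rose (median -0.85, adjusted p = 2.72e-04, and adjusted p = 0.336 with an estimated correlation). Cholesterol synthesis genes fell, 9 of 13 (median -1.07, adjusted p = 0.00163, and adjusted p = 0.364 with an estimated correlation), with Insig1 lower by 1.97 and Cyp51 by 1.74. The unfolded protein and heat shock response rose, 10 of 16 against 1 lower (median 0.70, adjusted p = 0.0142, and adjusted p = 0.255 with an estimated correlation), including Hsph1 by 2.47. There were 5116 calls, 2768 higher and 2348 lower, and median scaling gave 3267 higher and 1779 lower while moving the median over all genes from 0.03 to 0.16.

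In KO cells interferon-stimulated and TLR primary response genes rose as well. At 2 h Cmpk2 rose by 8.03 ± 0.19, Oasl1, an antiviral gene, by 7.42 ± 0.16 and Cd40 by 5.78 ± 0.10, and Cxcl9 was at least 229-fold higher. Per1 fell by 4.68 ± 0.14 and Cxcr4, a homing receptor, fell by 4.08 ± 0.15. All 29 interferon-stimulated genes rose (median 4.16, adjusted p = 4.16e-23), as did 24 of 27 TLR primary response genes with 1 lower (median 1.82, adjusted p = 9.67e-12). Both had an adjusted p = 0.0711 with an estimated correlation. At 12 h Irf7 rose by 7.31 ± 0.11, Il10 by 4.04 ± 0.12 and Hspa1a, a heat shock protein, by 4.52 ± 0.16, while Mrc1 fell by 4.94 ± 0.19. All 29 interferon-stimulated genes were higher (median 4.23, adjusted p = 3.68e-20, and adjusted p = 0.0729 with an estimated correlation). Cholesterol synthesis genes fell, 11 of 13 against 1 higher (median -1.48, adjusted p = 0.00202, and adjusted p = 0.453 with an estimated correlation), with Dhcr7 lower by 2.94. KO cells had 5698 calls at 2 h, 2253 higher and 3445 lower, and 5713 at 12 h, 2584 higher and 3129 lower. Across genes, which are not independent replicates, the responses of the genotypes correlated at 0.936 at 2 h and 0.936 at 12 h. Of 4781 genes called in both genotypes at 2 h 16 moved in opposite directions, and of 4693 at 12 h 29 did. Median scaling gave 1651 higher and 4241 lower at 2 h in KO cells and moved the median over all genes from -0.15 to -0.33.

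The next question was what NFAT1 loss changed before stimulation. Unstimulated KO cells had higher levels of genes that mark maturing dendritic cells. Cd40 was higher by 1.16 ± 0.10 (adjusted p = 0.00230), with 2 of 3 other probes past the threshold and 1 at 0.10, Ccr7, the receptor that guides dendritic cells to lymph nodes, by 1.22 ± 0.11 and Tnfsf4, the OX40 ligand, by 1.01 ± 0.11, and Ccl22, a chemokine of mature dendritic cells, by 0.80 ± 0.10. Of the 22 maturation genes measured 10 were higher, 0 lower and 12 not passing, and 19 passed when adjusted over the list alone (median 0.70, adjusted p = 2.96e-19, and adjusted p = 0.0210 with an estimated correlation). Ptgis, prostacyclin synthase, was lower by 4.46 ± 0.34 (adjusted p = 0.00230), Sdc4, syndecan 4, by 1.31 ± 0.17, and Serinc3 by 0.92 ± 0.10. Sys1, a Golgi trafficking gene, was higher by 1.70 ± 0.19, Il18r1, a chain of the interleukin 18 receptor, by 1.48 ± 0.18, Clu, clusterin, by 1.42 ± 0.24 and Atp9a by 1.38 ± 0.21, where 0 of 1 other probe moved past the threshold. That other Atp9a probe moved the same way, by 1.04 (unadjusted p = 0.00226 in limma).

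Smaller shifts were seen in other groups of unstimulated cells. TLR primary response genes had a median of 0.27 (3 higher, 0 lower, 24 not passing, 10 adjusted over the list alone, adjusted p = 2.62e-05), with Traf1 higher by 0.95 and Relb by 0.70, and interferon-stimulated genes a median of 0.23, or 0.12 with undetected members at their bound (1 higher, 28 not passing, 5 adjusted over the list alone, adjusted p = 1.32e-04), with Usp18 higher by 1.06 and 1 of its 2 other probes past the threshold. Both had an adjusted p = 0.493 with an estimated correlation. Immediate early genes (median 0.25, or 0.14 with bounds, adjusted p = 0.0171) and glycolysis genes (median -0.16, adjusted p = 0.00233) also had an adjusted p = 0.493 with an estimated correlation, and cell cycle genes (median 0.23, adjusted p = 0.0179) one of 0.631. The immediate early list had an adjusted p = 0.772 without the second unstimulated KO array and 0.113 without the second unstimulated WT array. For cell cycle genes it was 0.986 and 0.0766 without the second KO or first WT array, and for glycolysis genes 0.130 without the first KO array. Of the conventional dendritic cell markers Batf3 was higher by 0.68 and Sirpa lower by 0.71, and the list as a whole was not called (median 0.32, adjusted p = 0.237). The neutrophil markers had a median of -0.35 (1 higher, 17 not passing, adjusted p = 0.152).

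The count in unstimulated cells was 95 genes, 76 higher and 19 lower, and it depended on single arrays. It was 6 and 2 without the first or second unstimulated WT array, 213 and 13 without the first or second unstimulated KO array, 63 without either WT array at 2 h, and 54 without either KO array at 12 h. Of the 35 genes of this contrast that the naming rule gave, Cd40 and Ptgis kept their calls with any 1 array left out and 33 did not. Other settings gave 235 without background correction, 246 with a variance trend and robust fitting, 58 with median scaling, and 0 in limma from the 4 arrays alone, where 1183 genes had an unadjusted p under 0.05. Around Nfatc2 on chromosome 2 the 100 nearest tested genes held 9 of the 95 calls, against a mean of 1.01 over 6982 windows of 100 neighbouring genes. They were Serinc3, Sdc4, Ptgis and Sys1, Cd40, Atp9a and Ptk6, and Ppdpf (0.83) and Helz2 (0.91), which were picked out after their values were seen. The list of chromosome 2 neighbours fixed beforehand, an overlapping set of 21 tested genes, had 1 called higher and 1 lower. Of all tested genes 1.06% were called. For that list camera gave an adjusted p = 0.861, but it tests for a shift in 1 direction, which genes moving both ways would not show.

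**Figure D2:**
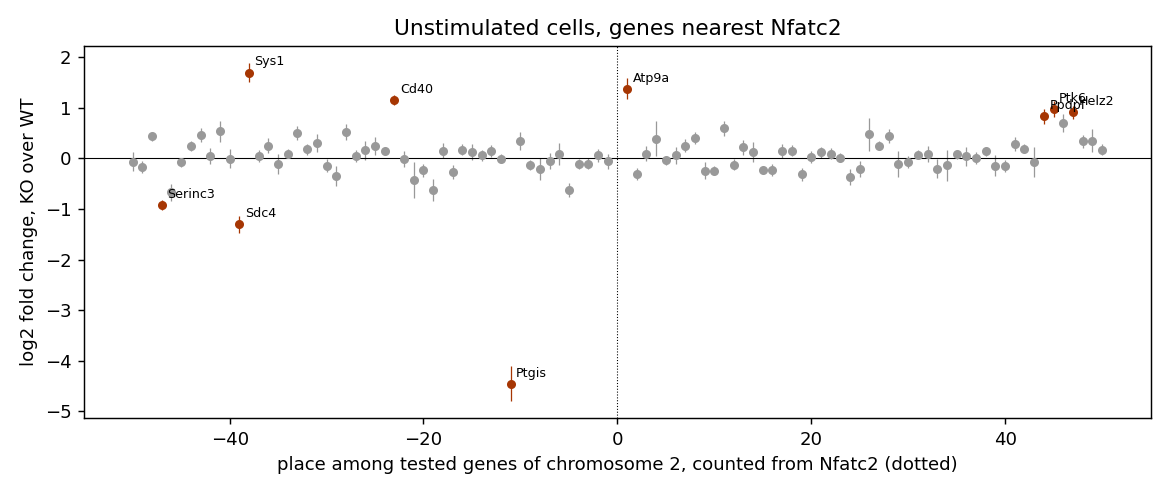
KO against WT in unstimulated cells for the 100 tested genes nearest Nfatc2, in chromosome order, as log2 difference with its standard error from n = 2 arrays per group, called genes in red. The 9 called genes lie on both sides of Nfatc2, from Ptgis at -4.46 to Sys1 at 1.70.

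At 2 h after Pam3CSK4 KO cells had less of several early inflammatory transcripts. Ptgs2, which encodes the inducible cyclooxygenase 2, was lower by 1.96 ± 0.19 (adjusted p = 6.13e-04), Csf2, the growth factor GM-CSF, was at least 2.42-fold lower, and Nos2, inducible nitric oxide synthase, was lower by 1.09 ± 0.18. The immediate early genes Ier3 and Egr2 were lower by 1.02 ± 0.14 and 0.80 ± 0.12, and Slc40a1, the iron exporter ferroportin, by 1.92 ± 0.24. Ptgis, lower in unstimulated KO cells, was lower at 2 h too, by 4.50 ± 0.34 in the fit of all arrays. It was detected on 1 of 2 KO arrays there. Higher in KO cells were Mylk, myosin light chain kinase, by 2.02 ± 0.17, Il18r1 by 2.01 ± 0.18, Ffar4, a receptor for long-chain fatty acids, by 1.68 ± 0.17 and Ccl22 by 1.07 ± 0.10. Sys1 was at least 4.33-fold higher and En2 at least 2.51-fold, since WT cells at 2 h were not above background. Of the interferon-stimulated genes Oasl1 and Cmpk2 were higher by 0.88 ± 0.16 and 0.77 ± 0.19. Oas3 was lower by 0.58 ± 0.15, with 0 of 1 other probe past the threshold. Among chemokines Cxcl9 was higher by 1.28 ± 0.16 and Cxcl1 lower by 0.74 ± 0.13. These interferon-stimulated and chemokine calls are given from the fit of all arrays only, and whether each holds without a single array is not stated here. Of 83 called genes that the naming rule gave for this contrast, 37 lost their call without some single array.

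Maturation genes were again higher at 2 h, 13 of 22 with 0 lower and 15 adjusted over the list alone (median 0.54, adjusted p = 5.23e-10, and adjusted p = 0.112 with an estimated correlation), including Fscn1, an actin bundler of dendrites, by 1.27 ± 0.15 and Cd80 by 1.03 ± 0.13. The oxidative stress response was lower, 5 of 12 with 7 adjusted over the list alone (median -0.54, or -0.34 with bounds, adjusted p = 7.28e-05, and adjusted p = 0.299 with an estimated correlation), with Srxn1 lower by 0.88 ± 0.10 and Nqo1 by 0.88 ± 0.14, where 0 of 1 other Nqo1 probe moved past the threshold. Of the unfolded protein response genes 6 of 16 were lower (7 adjusted over the list alone, median -0.27, adjusted p = 0.00791, and adjusted p = 0.458 with an estimated correlation), with Ddit3, a stress transcription factor, lower by 0.83 ± 0.12. Inflammatory effectors (0 higher, 5 lower, median -0.29, adjusted p = 0.00703) and pattern recognition receptors (2 higher, 6 lower, median -0.30, adjusted p = 0.00797), with Tlr2 itself lower by 0.63 ± 0.10, had an adjusted p = 0.505 with an estimated correlation. TLR primary response genes (0 higher, 7 lower, 20 not passing, median -0.12, adjusted p = 0.0491, and adjusted p = 0.572 with an estimated correlation) lost their call in 7 alternatives. The adjusted p was 0.179 without the second WT array at 2 h, 0.105 without the second KO array at 2 h, 0.0531 and 0.0534 without the first or second unstimulated WT array, and 0.268 with all probes.

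Markers of other cells moved as well. Irf8, Irf4 and Batf3, transcription factors of conventional dendritic cells, were higher in KO cells at 2 h by 1.39 ± 0.17, 1.07 ± 0.15 and 0.81 ± 0.11, and 4 of the 12 markers of that list were higher and 0 lower (median 0.28, adjusted p = 0.0947). Neutrophil and granulocyte precursor markers were lower, with 4 lower, 1 higher and 13 not passing, and 11 adjusted over the list alone (median -0.85, or -0.49 with bounds, adjusted p = 0.00422, and adjusted p = 0.572 with an estimated correlation), and without the second WT array at 2 h the adjusted p was 0.0869. The granule genes Ngp and Camp were at -1.85 ± 0.43 and -1.66 ± 0.46, and the eosinophil gene Prg2 at -1.71 ± 0.49. These 3 calls ended when 1 of 3, 10 and 8 arrays was left out, with adjusted p up to 0.113, 0.186 and 0.216. Itgb2l, on the same neutrophil list, was higher by 1.05 ± 0.15. Cell cycle genes had a median of 0.42, or 0.40 with bounds (2 higher, 20 not passing, 10 adjusted over the list alone, adjusted p = 0.00103, and adjusted p = 0.530 with an estimated correlation). The count at 2 h was 1296 genes, 725 higher and 571 lower. It was 466 and 844 without the first or second WT array at 2 h, 679 and 671 without the first or second KO array, and 521 from the 4 arrays of the contrast alone.

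At 12 h KO cells had more of the interferon-induced transcripts. Nos2 was higher by 2.18 ± 0.18 (adjusted p = 2.82e-04), Cxcl9 by 2.02 ± 0.16, Oasl1 by 1.88 ± 0.16 and Il10, an anti-inflammatory cytokine, by 1.39 ± 0.12. Il15, which sustains NK and memory T cells, was higher by 1.43 ± 0.13 and Cish, an inhibitor of cytokine signalling, by 1.64 ± 0.15. Cxcl5 was lower by 1.74 ± 0.25, Ednrb, the endothelin receptor B, by 1.66 ± 0.30 and Rasgrf1, a Ras exchange factor, by 1.56 ± 0.17. Arhgap8 was at least 3.85-fold higher and the cytokine receptor gene Il31ra at least 2.60-fold. Elovl6, a fatty acid elongase, was at least 2.41-fold lower.

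Of the 29 interferon-stimulated genes 24 were higher, 0 lower and 5 not passing at 12 h, and 27 passed when adjusted over the list alone (median 0.81, adjusted p = 3.03e-18, and adjusted p = 0.105 with an estimated correlation), including Isg20 by 1.86 ± 0.15 and Irf7 by 1.13 ± 0.11. Maturation genes were higher, 19 of 22 with 21 adjusted over the list alone (median 0.95, adjusted p = 3.51e-17, and adjusted p = 0.0299 with an estimated correlation), among them Cd70 by 1.64 ± 0.12, Tnfsf4 by 1.41 ± 0.11 and Cd83 by 1.31 ± 0.11. Cytokines (7 higher, 0 lower, median 0.34, adjusted p = 0.00133, and adjusted p = 0.208 with an estimated correlation) and chemokines (8 higher, 2 lower, median 0.26, adjusted p = 0.00497, and adjusted p = 0.105 with an estimated correlation) moved with them, the latter with Ccl12 higher by 1.84 ± 0.18 and Cxcl1 lower by 0.71 ± 0.13. Among lupus and dying-cell clearance genes 11 were higher and 1 lower of 22 (median 0.39, adjusted p = 9.07e-04, and adjusted p = 0.105 with an estimated correlation), with Mertk, a receptor for dying cells, higher by 1.12 ± 0.14 and the Fc receptor gene Fcgr3 by 0.80 ± 0.09. Both presentation lists were higher, MHC class II with 6 of 17 (median 0.20, adjusted p = 0.00200, and adjusted p = 0.105 with an estimated correlation), H2-DMb2 by 1.20 ± 0.18 among them, and MHC class I with 8 of 18 (median 0.39, adjusted p = 3.71e-04, and adjusted p = 0.122 with an estimated correlation), with Psmb9 higher by 0.64 ± 0.12.

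Cholesterol synthesis genes were lower in KO cells at 12 h. Of the 13 cholesterol synthesis genes 11 were lower, 0 higher and 2 not passing, and 11 passed when adjusted over the list alone (median -1.02, adjusted p = 1.31e-06, and adjusted p = 0.208 with an estimated correlation). Fdps was lower by 1.47 ± 0.23 and Sqle, squalene epoxidase, by 1.20 ± 0.19. The oxidative stress response (0 higher, 5 lower, median -0.37, adjusted p = 0.00671, and adjusted p = 0.208 with an estimated correlation) included Nqo1, lower by 0.99 ± 0.14 with 0 of 1 other probe past the threshold, and oxidative phosphorylation (0 higher, 4 lower, 21 not passing, median -0.18, adjusted p = 0.00255) had the same adjusted p = 0.208 with an estimated correlation. Glycolysis and hypoxia genes were not called (2 higher, 0 lower, median 0.10, adjusted p = 0.0641), with Vegfa, a vascular growth factor, higher by 1.51 ± 0.22. Conventional dendritic cell markers were higher, 7 of 12 with 0 lower (median 0.90, or 0.84 with bounds, adjusted p = 7.33e-04, and adjusted p = 0.105 with an estimated correlation), with Irf4 at 1.72 ± 0.15 and Zbtb46 at 1.07 ± 0.15. Neutrophil markers were not called as a list (1 higher, 2 lower, median -0.12, or 0 with bounds, adjusted p = 0.434). S100a8 and S100a9, neutrophil calcium-binding proteins, were at -1.47 ± 0.34 and -1.92 ± 0.51, and each lost its call without any 1 of the 4 arrays at 12 h (adjusted p up to 0.0803 and 0.153). The count was 1665 genes, 818 higher and 847 lower. It was 775 and 971 without the first or second WT array at 12 h, 669 and 1024 without the first or second KO array, 833 from the 4 arrays of the contrast alone, and 451 without both arrays whose columns were identical in the authors' second table, an alternative chosen after seeing the data. In that last fit the calls of cytokines (adjusted p = 0.0706), oxidative phosphorylation (adjusted p = 0.0671), immediate early genes (adjusted p = 0.203), TLR feedback genes (adjusted p = 0.119), Sqle and Cxcl10 ended, Cxcl10 being at 2.32 ± 0.46 with all arrays and lost also without either of these 2 arrays (adjusted p up to 0.0618).

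**Figure D3:**
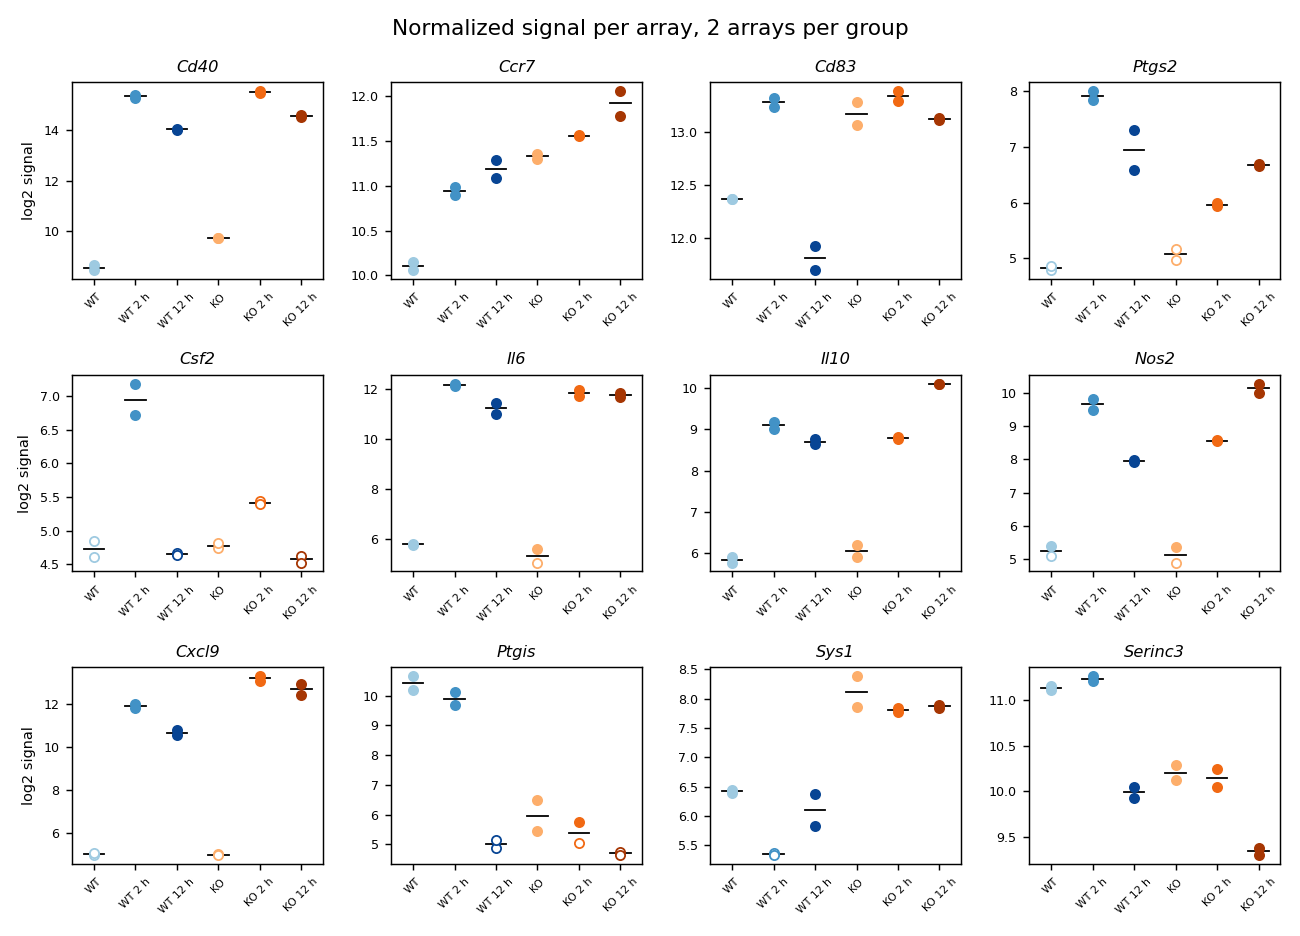
Normalized log2 signal of 12 genes on each of the 12 arrays by group, filled where the probe was detected on that array and open where it was not, with bars at the group means of n = 2 arrays. Ptgs2 and Csf2 lie lower in KO than in WT cells at 2 h, and Nos2 lies lower in KO cells at 2 h (-1.09) and higher at 12 h (2.18). Ptgis lies lower in KO cells when unstimulated (-4.46) and at 2 h (-4.50), and is not detected in either genotype at 12 h.

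**Figure D4:**
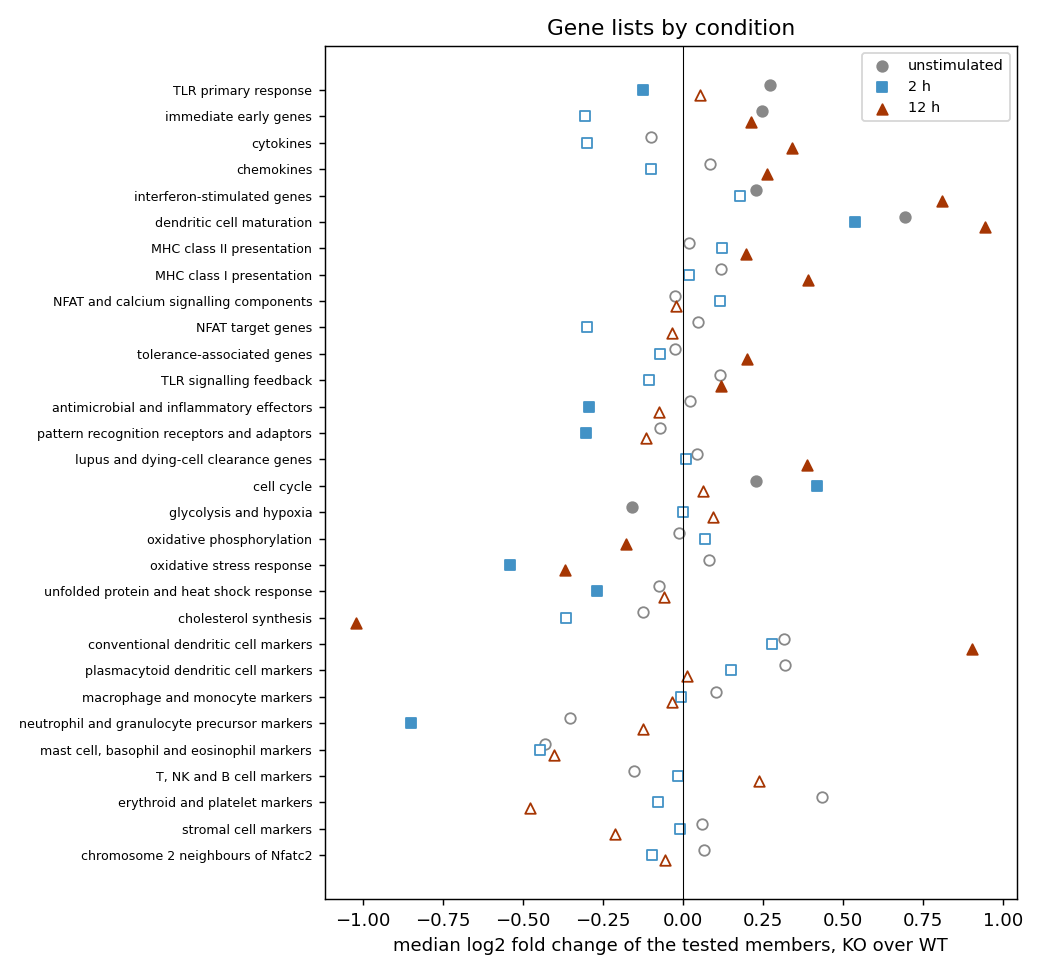
Median log2 difference of KO against WT over the tested genes of each of the 30 lists (circles unstimulated, squares 2 h, triangles 12 h), filled where camera with a preset correlation gave an adjusted p under 0.05. Maturation genes are filled in all 3 conditions at 0.70, 0.54 and 0.95, and interferon-stimulated genes reach 0.81 at 12 h.

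Averaged over the 3 conditions, 2132 genes were called, 1079 higher in KO cells and 1053 lower. Mylk was higher by 1.74 ± 0.10, the transcription factor gene Dmrta2 by 1.31 ± 0.08, Clu by 1.44 ± 0.14 and Klrk1, the activating receptor NKG2D, by 1.21 ± 0.13. Lower were Gal, galanin, by 1.46 ± 0.21, Prg2 by 1.35 ± 0.28, S100a9 by 1.34 ± 0.29, Sdc4 by 1.28 ± 0.10 and Fcna, ficolin A, by 1.28 ± 0.21. Maturation genes were higher, 20 of 22 with 22 adjusted over the list alone (median 0.72, adjusted p = 2.51e-19, and adjusted p = 0.0208 with an estimated correlation). Interferon-stimulated genes (21 higher, 0 lower, median 0.36, adjusted p = 6.24e-13, and adjusted p = 0.307 with an estimated correlation) and cholesterol synthesis genes (0 higher, 10 lower, median -0.53, adjusted p = 1.63e-04, and adjusted p = 0.363 with an estimated correlation) were called in opposite directions. Neutrophil markers were lower, 6 of 18 with 1 higher (median -0.45, adjusted p = 0.0128, and adjusted p = 0.554 with an estimated correlation). In all 3 conditions 44 genes were called higher and 3 lower, the latter being Sdc4, Serinc3 and Qpct, glutaminyl cyclase, the last named after its values were seen. Of the genes higher at 2 h and at 12 h, which share no arrays, 284 were the same where independent lists would share 66.1, and of those lower 127 where they would share 53.9. Both contrasts used the same estimate of each gene's spread, which favours shared calls, so 66.1 and 53.9 may be too low as baselines. Another 51 genes were called in opposite directions at the 2 times. Without both arrays with identical columns the count of the averaged contrast was 1361.

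Whether NFAT1 loss changed the response to Pam3CSK4 was tested as the difference between the genotypes' responses. At 2 h the rise of some genes was smaller in KO cells. The difference was -1.86 ± 0.34 for Slc40a1, -1.26 ± 0.20 for Ier3, -1.17 ± 0.22 for Il1b, an inflammatory cytokine, and -0.92 ± 0.15 for Srxn1, with 1 of its 2 other probes past the threshold. These 4 calls ended without any 1 of 10, 6, 12 and 8 arrays, with adjusted p up to 0.132, 0.0966, 0.117 and 0.0957. Ptgs2, Csf2 and Ier2 were called lower too, but were not above background in at least 1 of the groups compared, so the size of their difference was not measured. Gcnt1, a glycosyltransferase gene, had a response higher in KO cells by 1.5 ± 0.12 (adjusted p = 0.00303), though 0 of 1 other probe moved past the threshold. Negative list differences were seen for TLR primary response genes (0 higher, 3 lower, 24 not passing, 12 adjusted over the list alone, median -0.49, adjusted p = 6.35e-08, and adjusted p = 0.304 with an estimated correlation), immediate early genes (0 higher, 2 lower, median -0.57, adjusted p = 1.24e-04, and adjusted p = 0.469 with an estimated correlation) and the oxidative stress response (0 higher, 2 lower, 9 adjusted over the list alone, median -0.77, adjusted p = 9.68e-07, and adjusted p = 0.295 with an estimated correlation). Some immediate early genes fell at 2 h in WT cells, among them Fosb by 2.63 and Egr2 by 2.07, so a negative difference is not a smaller response for all members. NFAT target genes, with Ptgs2 and Csf2 as the 2 called of 11, had a median of -0.37 (adjusted p = 0.0367, and adjusted p = 0.304 with an estimated correlation), and lost the call without the second unstimulated WT array (0.137), the first WT array at 2 h (0.0914), the second WT array at 12 h (0.0795) or either KO array at 2 h (0.0544 and 0.0667). With all kept probes its median was -0.06 (adjusted p = 0.169), and without the filter on dim probes it was 0.02 (adjusted p = 0.233). Inflammatory effectors had a median of -0.34 (adjusted p = 0.00557, and adjusted p = 0.469 with an estimated correlation), and adjusted p values of 0.110 and 0.0528 without the first unstimulated WT array or the second WT array at 2 h. With all kept probes its median was -0.17 (adjusted p = 0.0544).

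In this contrast 97 genes were called, 50 higher and 47 lower. It was 1 without the first unstimulated WT array, where Gcnt1 was left, and 3 without the second (Gcnt1, Tob1 and En2). Without the first or second WT array at 2 h it was 21 and 44, without the KO arrays at 2 h 32 and 42, without the second unstimulated KO array 42, and without either KO array at 12 h 58. Median scaling gave 29 higher and 43 lower.

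At 12 h the response of interferon-induced genes was larger in KO cells. The difference was 1.96 ± 0.27 for Cmpk2, 1.86 ± 0.22 for Oasl1, 1.95 ± 0.25 for Ccl12, a monocyte attractant, and 1.71 ± 0.22 for Calhm6. Cxcl9 and Nos2 were called higher too, but were not above background on every unstimulated array, so the size of their difference was not measured. Ptgis was also called with a positive difference. It was not above background at 12 h in either genotype, so the size of its difference was not measured either. Ndrg1, a hypoxia-responsive gene, differed by 2.03 ± 0.19 (adjusted p = 0.00314), Mertk by 1.58 ± 0.19 and Cish by 1.64 ± 0.21, and Rasgrf1 by -2.46 ± 0.24. These 8 genes with values kept their calls with any 1 array left out. The interferon-stimulated genes (8 higher, 0 lower, 21 not passing, 17 adjusted over the list alone, median 0.60, adjusted p = 2.58e-11) and cytokines (3 higher, 0 lower, median 0.35, adjusted p = 1.13e-04) had an adjusted p = 0.220 with an estimated correlation. Cholesterol synthesis genes had a negative difference as a group (0 called over all genes, 11 of 13 adjusted over the list alone, median -0.82, adjusted p = 1.66e-05, and adjusted p = 0.293 with an estimated correlation). Conventional dendritic cell markers (1 higher, Irf4 by 1.18, median 0.45, adjusted p = 5.76e-04) and lupus and clearance genes (5 higher, median 0.28, adjusted p = 1.16e-04) had an adjusted p = 0.135 with an estimated correlation, and Irf4 lost its call without any 1 of 6 arrays (adjusted p up to 0.0919).

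At 12 h 236 genes differed in response, 142 higher and 94 lower. The count was 39 and 52 without the first or second unstimulated WT array, 68 and 98 without the WT arrays at 12 h, 129 and 89 without the unstimulated KO arrays, 157 and 155 without the KO arrays at 2 h, 36 without the first KO array at 12 h, and 10 without both arrays with identical columns. Rasgrf1 and Ndrg1 kept their calls in that last fit.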

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

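The tests of the window around Nfatc2, of exposure before harvest, of the cell mix, of maturation genes outside that window and of a higher starting level were chosen only after the result each concerns had been seen. The results below are those in which the 2 genotypes differed in their response to Pam3CSK4 by a test of the difference itself. There were 97 such genes at 2 h and 236 at 12 h.

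At 2 h the response of KO cells less that of WT cells was positive for Amigo2 (1.70), Gcnt1 (1.5), Tob1 (1.37), Zfp296 (1.33), Eps8 (1.33), Ppif (1.24), Arhgap27 (1.22) and Hhex (1.20). It was negative for Slc40a1 (-1.86), Foxq1 (-1.65), Ccno (-1.59), Foxn2 (-1.41), Gadd45a (-1.30), Ier3 (-1.26), Id1 (-1.26) and Phlda1 (-1.25), and for the list members Ptgs2 (-2.20), Ier2 (-1.49), Nqo1 (-1.19), Il1b (-1.17) and Srxn1 (-0.92). Ptgs2 and Ier2 were not above background in at least 1 of the groups, so their values are not exact, and 0 of 1 other probe of Gcnt1 and of Nqo1 and 1 of 2 of Srxn1 passed. Of 29 genes named for this contrast 28 lost their call without some single array, all but Gcnt1. List medians were -0.49 for TLR primary response genes, -0.57 for immediate early genes, -0.37 for NFAT target genes, -0.34 for inflammatory effectors and -0.77 for the oxidative stress response. With an estimated correlation the adjusted p of these 5 lists lay between 0.295 and 0.469.

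At 12 h the difference was positive for Cxcl10 (2.97), Ndrg1 (2.03), Cmpk2 (1.96), Ccl12 (1.95), Fcgr4 (1.90), Oasl1 (1.86), Gm6377 (1.78) and Calhm6 (1.71). It was negative for Rasgrf1 (-2.46), Apol7c (-1.74), Pank1 (-1.59), Ppp1r9a (-1.47), Nqo1 (-1.30), Rpp38 (-1.17), Pxylp1 (-1.09) and Acpp (-1.08). Among list members it was positive for the cytokine and interferon-induced genes Il10 (1.19), Il15 (1.21), Il1rn (1.02), Isg20 (1.58) and Igtp (0.92), and for the surface molecules Cd200 (1.54), Cd80 (1.12) and Cd70 (1.04). The clearance and Fc receptor genes Mertk (1.58) and Fcgr3 (0.92), and Dnase1l3 (1.60), Vegfa (1.44) and Irf4 (1.18), were positive too. Isg20 and Dnase1l3 were not above background on every array, so their values are not exact, and 0 of 1 other probe of Nqo1, Acpp and Il1rn passed. Of 40 genes named for this contrast 27 lost their call without some single array, among them Cxcl10 and Fcgr4 (adjusted p up to 0.149 and 0.137) and Il10 (up to 0.0581). List medians were 0.60 for interferon-stimulated genes, 0.35 for cytokines, 0.28 for lupus and clearance genes, 0.36 for glycolysis, 0.45 for conventional dendritic cell markers and 0.24 for tolerance-associated genes. They were 0.26 for MHC class II, 0.21 for maturation genes and 0.22 for MHC class I, and -0.82 for cholesterol synthesis, -0.39 for the oxidative stress response and -0.16 for oxidative phosphorylation. With an estimated correlation the adjusted p of these 12 lists lay between 0.135 and 0.314. The MHC class I call also ended without any 1 of 4 arrays (adjusted p from 0.067 to 0.0781) and without both 12 h arrays of identical columns (0.239). The maturation call ended without the first unstimulated KO array (0.0683), and oxidative phosphorylation with median scaling (0.104), without the first KO array at 12 h (0.0833) and without both 12 h arrays (0.172).

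Of 3 patterns weighed, the first is the set of genotype calls in unstimulated cells, which the design would put down to NFAT1 loss. DNA carried along with the targeted locus is a candidate explanation for the calls next to Nfatc2, since 99.9% of windows of neighbouring genes held fewer calls. Of the 9 genes called there 5 were called the same way in all 3 conditions. So were 47 of all 95 called genes, so that share among called genes is not particular to this window. As a count, though, these 5 genes were the most found in any window. The mean was 0.482, and 99.9% of windows held fewer. The window stood out less at 2 h (20 calls, with fewer in 89.9% of windows) and at 12 h (24 calls, 87.1%). A mismatch under single probes was tested only for the 26 of 95 called genes with another kept probe, and does not account for these as a set, since 71.1% of 38 other probes moved the same way at an unadjusted p under 0.05 and 0 the opposite way. The strain of the mice is not given in the sources used here, so the first explanation stays open for these 9 genes.

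The second is the higher level of maturation genes in unstimulated KO cells. Of the 22 genes 1, Cd40, lay among the genes nearest Nfatc2, and the list median was 0.69 without it and 0.70 with it. The pattern is therefore not made up of genes next to Nfatc2. Leaving out 1 of 22 genes could hardly move a median, so an effect of neighbouring DNA on genes elsewhere stays open. Exposure of the KO cultures to a stimulus before harvest could not be told apart from an effect of genotype, since the 100 genes that rose most at 2 h in WT cells had a median difference of 0.14, the mean of 0.11 and 0.17 with each unstimulated WT array in turn. Another mix of cells in the cultures could not be excluded either, as conventional dendritic cell markers had a median of 0.32 with 1 called higher and 1 called lower.

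The third is the smaller rise of TLR primary response genes in KO cells at 2 h. A higher starting level alone would not give the 7 of 27 members called lower, with 0 called higher, in KO cells at 2 h. The call of that list at 2 h itself ended in several alternatives. The higher start was still a large part of the pattern. The list median was 0.27 in unstimulated cells and -0.12 at 2 h, against -0.49 for the difference between responses. Compression of bright probes does not account for the list as a whole. The interaction median of the 13 brighter genes was 0.32 above that of the 14 dimmer ones, -0.31 against -0.63. Such a split cannot show that the brighter genes themselves were free of compression, so a part in their values stays open. Exposure before harvest and another mix of cells were not tested for this pattern, so they stay open beside genotype.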

How the results depend on the processing

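Of 976 called gene results, 790 kept their call with any 1 array left out, and each array left alone in its group was assumed to vary like the other groups. Of 122 called list results, 119 lost the call with an estimated correlation and 3 kept it, which were maturation genes in unstimulated cells, at 12 h and on average. Leaving out 1 array gave 2 to 213 genotype calls in unstimulated cells, 466 to 1315 at 2 h and 669 to 1667 at 12 h, and 1 to 93 interaction calls at 2 h and 36 to 185 at 12 h. For the average it gave 1526 to 2005. Without background correction the counts were 235 in unstimulated cells and 324 and 538 for the interactions at 2 h and 12 h, and with a variance trend and robust fitting they were 246, 300 and 526. Median scaling gave 58 in unstimulated cells, and no filter on dim probes 150 for the interaction at 12 h. With only the arrays of the contrast they were 0, 521 and 833 for the genotype in unstimulated cells, at 2 h and at 12 h, where limma gave 1183 at an unadjusted p under 0.05 for the first, and 42 and 98 for the interactions. A 2-fold minimum left 29, 226, 249 and 62 for the genotype in the 3 conditions and on average, 1920 and 2112 for WT and 1877 and 2055 for KO responses, 1698 for time in WT, and 62 and 115 for the interactions. Without both 12 h arrays of identical columns there were 451 genotype calls at 12 h, 1361 on average and 10 interaction calls. Deviations of arrays with the same replicate number correlated between -0.0276 and 0.226 over 15 pairs of groups, with 0.199 to 0.226 among the 3 WT groups. Among the KO groups the correlations were 0.065 to 0.151. Not every pair was above 0.1, so the number was not taken to pair the samples. That rule also counts pairs of a WT and a KO group, which cannot share an animal. A pairing within a genotype, above all in WT cells, therefore stays open. The replicate block gave 150 calls in unstimulated cells, and other counts stayed within 1.5 times. With the block the adjusted p was 0.0664 for NFAT target genes in the interaction at 2 h and 0.0588 for TLR primary response genes in the genotype contrast at 2 h. Cd247 on average turned from 0.17 to -0.27 without the second KO array at 2 h and was 0.26 without the first KO array at 12 h, and its 1 other probe moved the opposite way past the threshold. The cell cycle list in unstimulated cells was at 0.00879 and 0.407 without the second or first unstimulated KO array. Neutrophil markers in the interaction at 12 h were at 0.11, and at -0.41 and 0.39 without those arrays. The cause was not tested. Gene results that lost their call against those that gained one numbered 47 and 7 with median scaling, 6 and 31 without background correction, 36 and 0 without the filter, 16 and 0 with all probes, 0 and 8 with a detection p under 0.01, 7 and 34 with the trend, 109 and 2 with only the arrays of the contrast, 108 and 2 without both 12 h arrays, and 3 and 0 without the genes nearest Nfatc2. The values of the second deposited table and a block for slides were not run, since the kind of values in that table is not settled and the sources used here give no slides. Signals near background limit what can be said of dim genes, as between 43.9% and 49.3% of probes were detected.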

Other observations

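Tolerance-associated genes were higher in KO cells at 12 h, 5 of 17 with 0 lower (median 0.20, adjusted p = 0.00529, and adjusted p = 0.105 with an estimated correlation), with Pdcd1lg2, a ligand of PD-1, higher by 1.51 ± 0.22. Of the TLR feedback genes 6 were higher, 1 lower and 13 not passing (median 0.12, adjusted p = 0.0126, and adjusted p = 0.201 with an estimated correlation), and the adjusted p was 0.0722 without the first KO array at 12 h and 0.119 without both 12 h arrays of identical columns. Immediate early genes had a median of 0.21, or 0.05 with bounds (5 higher, 1 lower, adjusted p = 0.0126, and adjusted p = 0.468 with an estimated correlation), and lost that call without the second WT array (0.0928) or the first KO array at 12 h (0.0532), or without both (0.203). In WT cells at 12 h stromal markers rose, 3 of 4 (median 1.94, or 1.40 with bounds, adjusted p = 0.0219, and adjusted p = 0.130 with an estimated correlation), including Igfbp7, a secreted binding protein, by 2.17 ± 0.19. Without the filter on dim probes that list had a median of 0.23 and was not called (adjusted p = 0.0758).

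Averaged over conditions, mast cell, basophil and eosinophil markers had a median of -0.43 (0 higher, 3 lower, 3 not passing, adjusted p = 0.0858), with Ear6, an eosinophil ribonuclease, lower by 0.71 ± 0.16. Macrophage markers were split at 12 h, 4 higher and 3 lower of 17 (median -0.03, adjusted p = 0.877), with Mertk higher by 1.12 ± 0.14. NFAT and calcium signalling components had 1 higher and 2 lower of 19 on average (median 0.03, adjusted p = 0.970), with Itpr2, a calcium channel of the endoplasmic reticulum, lower by 0.26 ± 0.06. Plasmacytoid dendritic cell markers (2 higher of 6, median 0.17, adjusted p = 0.277), T, NK and B cell markers (0 of 5, median 0.05, adjusted p = 0.555) and stromal markers (0 of 4, median -0.14, adjusted p = 0.675) were not called. Erythroid and platelet markers were not called either (0 of 3, adjusted p = 0.970), with a median of 0.07 and a mean of -0.02.

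The correlation of the 12 h genotype difference with the WT change over time was chosen as a test only after the result was seen. A hypothesis from these data is that KO cells at 12 h lie in part toward the 2 h state. Across genes, the 12 h genotype difference correlated at -0.292 and -0.240 with the WT change from 2 h to 12 h, once with each WT array at 12 h on either side so that no array was shared. The mean was -0.266. The lower scores of KO arrays at 12 h on the second principal component, which prompted the test, make a negative correlation hard to avoid, so it is no evidence for a slower passage between the states, which stays open. Other values run the other way. On the first principal component WT arrays lay at 18.0 and 19.4 at 2 h and at 33.6 and 38.1 at 12 h, and KO arrays further out at 12 h, at 41.1 and 45.5. Cholesterol synthesis genes fell from 2 h to 12 h in WT cells (median -1.07) and were lower still in KO cells at 12 h (median -1.02), so a slower passage of all genes does not account for the difference. The same correlation with the 12 h interaction was -0.333. Unstimulated arrays lay at 7.6 and 8.0 for WT and 8.1 and 8.9 for KO on the second component. Subtracting their difference could thus hardly change the sign, so no conclusion on a difference carried before stimulation is drawn from it. The correlation of the unstimulated genotype difference was 0.0854, so that difference did not itself run toward the 2 h state. Genes are not independent replicates, so no p is given for these correlations.

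The count for the average over conditions was compared with other splits of the arrays within conditions. In 1 of 100 splits as many genes were called, which was the real one with 2132, and the highest of the others had 1119. The median of the others was 0. If the arrays of a group came from the same culture or animal, differences between cultures or animals alone could put the real split first. The labels do not settle that, so the ranking cannot single out genotype.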
